A study of Mus musculus with 32 samples.

How the data were processed

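The samples were 32 messenger RNA libraries of mouse bone marrow-derived macrophages, 4 for each of 8 groups, wild type or Acod1 knockout crossed with no treatment, dexamethasone, LPS or both for 24 h. Groups and replicate numbers came from the sample labels, which do not say whether replicates came from separate mice, so p values measure the spread between these libraries, part of which may be technical. Marrow came from femur and tibia of C57BL/6J mice, RNA was isolated with RNeasy columns and libraries were made with a Novogene kit, per the labels.

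The deposited table holds raw counts of read pairs per gene, and 1 further column with the summed exon length in bases, which was not used. Per the file headers the authors counted with featureCounts 2.0.0 on exons, with paired reads, without regard to strand, grouped by gene identifier, on the GENCODE vM32 annotation. The submitters' processing notes name STAR as aligner, with a version not given in the sources used here, and the builds GRCm38 and mm10, while vM32 belongs to a later build. Of the 52029 identifiers found in the GRCm38 annotation used here, 1446 had the same coordinates as in the table, so the positions printed here are those of the deposited table. Of 56953 genes in the table, 4924 had identifiers without a match and kept their identifier; they held 0.846% of counts. File paths in the header place 22 libraries in sequencing lane 3 and 9 in lane 2, and 1 was merged. All WT libraries were in lane 3, and the KO libraries with LPS were all in lane 2.

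Library totals ran from 17559079 to 25049200 counts. Counts were analysed in R 4.3.3. Genes were kept by the default filterByExpr rule of edgeR 4.0.16, which left 14427, libraries were scaled by TMM, and the 8 group means were fitted together with the edgeR quasi-likelihood model (24 residual degrees of freedom). The biological coefficient of variation was 4.36%. Each of 14 contrasts was tested with the quasi-likelihood F test, two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 within the contrast. Contrasts were LPS against control, dexamethasone against control and dexamethasone plus LPS against LPS in each genotype, KO against WT in each treatment, the KO minus WT differences of the first 3 effects, and the difference of the dexamethasone effect with against without LPS in WT. Standard errors were derived from the F statistic and the fold change. CPM values use TMM-scaled library sizes. A fold against a group with 0 counts was computed against 3 counts over the group's 4 libraries, and a group with 1 to 3 counts got an exact binomial interval (95%) on the ratio of counts.

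Gene lists were written from textbook knowledge. They cover inflammatory cytokines and enzymes, chemokines, interferon-stimulated genes, NF-kappaB regulators, glucocorticoid receptor targets, scavenger genes, glycolysis, pyruvate entry, the TCA cycle, nuclear and mitochondrially encoded respiratory chain genes, NRF2, LXR and HIF1 targets, cholesterol synthesis, the integrated stress response, endoplasmic reticulum chaperones, cell cycle, MHC class II, macrophage identity, markers of neutrophils, B cells, T and NK cells, dendritic cells, mast cells, erythroid cells and fibroblasts, and genes reported to differ between mouse substrains. Lists with at least 2 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. An estimated correlation and fry were run beside it. The list called scavenger genes also holds efferocytosis and alternative-activation genes.

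Named genes followed a rule: Acod1, Nr3c1, Il1b, Il6 and Nos2 in every comparison; up to 4 members with the smallest adjusted p from each list described; and the 5 largest rises and 5 largest falls among called protein-coding genes with a mean of at least 5 CPM in a compared group and no overlap between the groups' libraries (for differences of effects, without this last condition). In genotype comparisons all tested genes within 5 Mb of Acod1 were counted as a group. Not every gene that the rule allows is reported here.

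Alternatives were RLE size factors, no normalization, no filter on low counts, DESeq2 1.42.0, an adjusted p under 0.01, a fit on the compared groups alone, a replicate block, and leaving out each library in turn. For the overlap of LPS-induced and dexamethasone-lowered genes the LPS libraries were split between the calls. After the data had been seen, a lane term, which leaves out the merged library, and the control and dexamethasone comparisons on lane 3 libraries alone were added. Replicates were compared by chi-square over gene counts: all 48 pairs within groups differed by more than sampling noise (2.05 to 18.4 per degree of freedom, median 2.95). The first fit had no replicate block. The tests were also run on simulated data. With 2-fold changes added to 50 genes in each direction, 92% and 98% were recovered in WT dexamethasone plus LPS against LPS and 94% and 90% in the difference between genotypes. For 1.25-fold changes the rates were 64% and 68%, and 52% and 50%. Among the calls 6.94% and 5.30% were false, and data without changes gave 0 edgeR calls over 13157 genes. Other splits of the compared libraries were refitted: all 35 splits for comparisons of 2 groups, and 60 random draws for differences of effects, which is fewer than 100 because each is a full fit. In these draws genotype labels were shuffled within each treatment, or dexamethasone labels within each LPS state.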

Results

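Messenger RNA was measured by sequencing in mouse bone marrow-derived macrophages, cells grown from femur and tibia marrow with L929 supernatant as the source of the growth factor M-CSF. The design crossed 2 genotypes with 4 treatments of 24 h, with 4 libraries in each of the 8 groups and 32 libraries in all. The genotypes were wild type (WT) and knockout (KO) of Acod1, also called Irg1, the gene for the enzyme that makes itaconate from the TCA cycle intermediate cis-aconitate. The treatments were none (control), the synthetic glucocorticoid dexamethasone at 100 nM, bacterial lipopolysaccharide (LPS) at 100 ng with no volume given, and dexamethasone together with LPS. The stated purpose was the anti-inflammatory action of glucocorticoids on LPS-treated macrophages and the part that Irg1 plays in it. Libraries held 17559079 to 25049200 assigned read pairs, and 14427 genes passed the filter on low counts. Levels below are group means in CPM, counts scaled to a common library size, ± SD over 4 libraries, and effects are log2 fold changes ± SE from edgeR with n = 4 libraries per group. Genes are called at a Benjamini-Hochberg adjusted p under 0.05, and WT and KO name the labels of the libraries. The gene lists, the main tests and the rule for which genes are named were fixed before the data were examined. The lane term, the fits on lane 3 libraries alone, the tests of explanations and a few genes named in the last parts came after the results were seen. Floors and counting intervals (95%) cover counting error alone, and a group with 0 counts is set to 3 counts over its 4 libraries.

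Acod1 was strongly induced by LPS in libraries of either label. In WT it went from 9.89 ± 1.26 CPM in control to 6483 ± 249 CPM with LPS, a log2 fold change of 9.35 ± 0.064, and in KO from 5.82 ± 0.747 to 4995 ± 133 CPM (9.75 ± 0.066). The annotation of the count table places the gene (ENSMUSG00000022126) on chromosome 14 from 103284413 to 103294009 on the plus strand, with 5 exons that cover 2623 bases. KO libraries had lower Acod1 than WT in control (-0.77 ± 0.092, adjusted p = 2.5e-07) and with LPS (-0.38 ± 0.040, adjusted p = 1.2e-09). With dexamethasone alone the difference was -0.83 ± 0.28 (adjusted p = 0.181), at 0.868 ± 0.310 CPM in WT and 0.490 ± 0.151 CPM in KO. With dexamethasone and LPS together Acod1 was higher in KO, 3933 ± 195 against 2738 ± 34.8 CPM (0.52 ± 0.041, adjusted p = 7.6e-16). In both treatments with LPS all KO libraries came from another sequencing lane than the WT libraries, and with a lane term, which rests on 1 library without LPS, neither difference was called (0.19 ± 0.56, adjusted p = 0.959, with LPS and 1.09 ± 0.54, adjusted p = 0.124, with both). The labels do not say which part of the gene was deleted, and gene-level counts pool all exons, so these reads do not check the KO label. Nr3c1, the gene for the glucocorticoid receptor, was at 148 ± 3.94 CPM in WT control and 144 ± 3.72 CPM in KO control (difference -0.04 ± 0.045, adjusted p = 0.868).

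**Figure D1:**
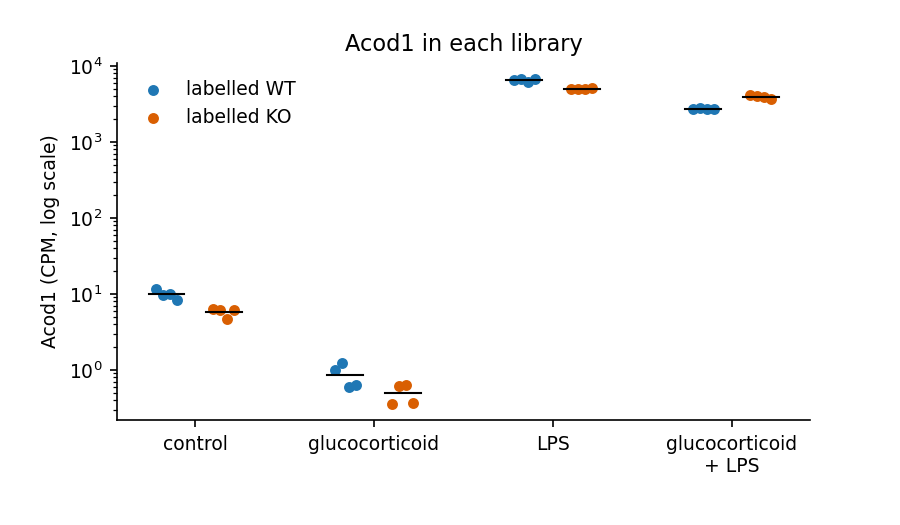
Acod1 in CPM on a log axis for each of the 8 groups; points are the 4 libraries of a group, blue for WT and orange for KO, and the black line marks their mean. The KO libraries with LPS sit between 4898 and 5187 CPM and the WT libraries between 6125 and 6675 CPM.

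Macrophage identity genes, such as Csf1r and Adgre1, dominated the marker signal in every group. Their 14 members summed to 28790 CPM in WT control, 30270 with dexamethasone, 20020 with LPS and 31780 with both, and to 19110 CPM in the lowest of the 32 libraries. The lysozyme gene Lyz2 alone held 18380, 20770, 7278 and 20950 CPM of the WT sums and carried the lower sum with LPS. Other members went both ways from WT control to LPS, such as Adgre1 (1135 to 4194 CPM) and Maf (550.5 to 70.14 CPM). Markers of other cells were far lower and differed between treatments. Neutrophil markers summed to 15.5 CPM in WT control, 96.2 with dexamethasone (95.7 of it from Mmp8), 72.3 with LPS and 28.9 with both. B cell markers summed to 103, 53.7, 0.538 and 3.42 CPM in the same order, nearly all of it from Ighm in control (101 ± 3.00 CPM). Dendritic cell markers ranged over libraries from 0.877 to 17.4 CPM, T and NK cell markers from 0.0489 to 4.96, fibroblast markers from 0.0512 to 4.06, mast cell markers from 0 to 1.15 and erythroid markers from 0.0501 to 0.852. Genes reported to differ between the C57BL/6J and C57BL/6N strains summed to 110.9 to 143.8 CPM. Nearly all of it came from Ide and Wdfy1 (63.85 and 48.39 CPM in WT control), so the sum does not tell the strain. Nnt, another member, was at 0.521 CPM in WT control and 0.675 CPM in KO control. Mitochondrially encoded genes took 0.438% ± 0.0554 of counts in WT control, 0.341% ± 0.0225 with LPS and 0.574% ± 0.0397 with both, against 0.280% ± 0.0326 and 0.348% ± 0.0191 in the 2 KO groups given LPS. Ribosomal protein genes took 3.06% ± 0.0445 in WT control, 1.48% ± 0.0889 with LPS and 2.39% ± 0.0361 with both, and 1.78% ± 0.0358 in KO with both. In WT with LPS, replicate 3 stood apart with 12.0% of counts in its 10 most abundant genes, against 10.67% to 11.02% in the other 3 libraries. The first 4 principal components of log2 CPM held 71.0%, 12.6%, 6.19% and 1.10% of the variance.

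The first comparison asked what LPS does to these macrophages before any glucocorticoid is considered. LPS raised inflammatory mediators by several orders of magnitude in WT. Il1b, the gene for interleukin-1 beta, went from 0.331 ± 0.154 to 8469 ± 670 CPM (14.61 ± 0.12), and Nos2, the inducible nitric oxide synthase, from 0.218 ± 0.0489 to 3850 ± 328 CPM (14.07 ± 0.12). The acute-phase gene Saa3 reached 22380 ± 3180 CPM (16.07 ± 0.12). Il6 was 1880-fold higher (counting interval 642 to 9100), with 3 counts over the control libraries, and Il1a 65200-fold higher (22300 to 316000), also with 3. Of 16 tested inflammatory cytokines and enzymes, 15 rose and 1 fell (camera adjusted p = 7.1e-09), with Ptges at 9.63 ± 0.072. Of 20 chemokines, 17 rose and 1 fell (adjusted p = 4.8e-06), including Ccl5 (9.65 ± 0.073), Cxcl2 (8.91 ± 0.11) and Cxcl1 (10.12 ± 0.16). All 17 NF-kappaB regulators rose (adjusted p = 2.3e-10), such as Traf1 (5.08 ± 0.052), Tnfaip3 (4.29 ± 0.049) and Socs3 (7.28 ± 0.090). Of 31 interferon-stimulated genes 30 rose and 1 fell, with Gbp2 at 3.82 ± 0.050 and Irf7 at 2.98 ± 0.050 (adjusted p = 2.4e-10, and adjusted p = 0.0818 with an estimated correlation).

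Metabolic genes changed as well. All 18 glycolysis genes rose in WT (camera adjusted p = 1.2e-13), among them the lactate exporter Slc16a3 (5.22 ± 0.053) and the glucose transporter Slc2a1 (5.37 ± 0.059). All 13 HIF1 target genes outside glycolysis rose (adjusted p = 2.6e-09), with Ero1l at 5.41 ± 0.059 and Bnip3 at 4.89 ± 0.061, and 18 of 19 NRF2 target genes rose (adjusted p = 2.5e-09), with Hmox1, the heme-degrading enzyme, at 4.12 ± 0.041. TCA cycle genes went both ways, 12 higher and 8 lower of 23 (adjusted p = 0.766), with a median above 0 and a mean below it. Of 52 nuclear-encoded oxidative phosphorylation genes, 31 rose and 11 fell (adjusted p = 0.0519). All 28 cell cycle genes fell (adjusted p = 3.4e-14), including Top2a (-6.25 ± 0.085) and Cenpe (-5.66 ± 0.11), and Cenpf was at least 1280-fold lower at 0 counts over the LPS libraries. Scavenger, efferocytosis and alternative-activation genes mostly fell, 13 of 19 (adjusted p = 0.0098), such as Gas6 (-5.86 ± 0.041) and the complement gene C1qc (-4.04 ± 0.049). Hpgd, which breaks down prostaglandins, was 14700-fold lower (2630 to 580000), and the transporter gene Slco2b1 at least 400-fold lower. In WT 10923 of the 14427 genes were called, 5393 higher and 5530 lower, and 4670 of them by 2-fold or more. KO libraries gave 10977 (5310 higher and 5667 lower), or 8380 with a lane term, since KO libraries with LPS were in lane 2 and KO controls in lane 3 except for 1 merged library. Higher genes outnumbered lower ones with RLE size factors (5535 and 5409 in WT, 5540 and 5414 in KO), with DESeq2 (5531 and 5415, 5546 and 5422) and, in WT, with the 2 groups fitted alone (5007 and 4994), while no normalization gave 3863 higher and 7463 lower in WT and 3864 and 7455 in KO. There Il1b changed by 15.02 ± 0.13, Nos2 by 15.21 ± 0.13, Slc16a3 by 5.15 ± 0.052, Ero1l by 5.01 ± 0.058 and Top2a by -6.22 ± 0.083, and Il6 was at least 1380-fold higher. The inflammatory, chemokine, NF-kappaB, glycolysis, HIF1, NRF2, cell cycle and scavenger lists were called in KO with the same directions, the weakest being the scavenger list at adjusted p = 0.0091. For these lists the counts adjusted over the list alone were identical in either genotype, and each call held with an estimated correlation. Camera, at its preset correlation, called as many lists in at least 1 other split of the libraries in 13 of the 14 comparisons. A split that keeps most of a group's libraries together holds part of a real effect, so such a match need not be chance. List p values stand beside the member counts throughout. With no normalization the median log2 change of all genes was -0.278 in WT and -0.272 in KO, against -0.02 and -0.032 with TMM.

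The second comparison asked what dexamethasone does without LPS. It raised known targets of its receptor and lowered interferon-stimulated and antigen-presentation genes in either genotype. Fkbp5, a co-chaperone of the receptor and a classical target, went from 29.9 ± 3.84 to 878 ± 12.8 CPM in WT (4.87 ± 0.062) and changed by 5.02 ± 0.062 in KO. Of 18 glucocorticoid receptor target genes, 14 rose in WT (camera adjusted p = 2.6e-14), and 14 in KO (adjusted p = 1.0e-14). They included Ddit4, an inhibitor of mTOR signalling (6.64 ± 0.10 in WT), Tsc22d3, which encodes the leucine zipper protein GILZ (3.60 ± 0.067), and the clock gene Per1 (2.65 ± 0.049). All 31 interferon-stimulated genes fell in WT (adjusted p = 1.7e-34) and in KO (adjusted p = 4.2e-34), with Ifit2 at -4.20 ± 0.077 and -3.78 ± 0.075. Cxcl10, an interferon-induced chemokine, fell by 5.00 ± 0.21 in WT and by 5.30 ± 0.23 in KO. Of 11 MHC class II and co-stimulation genes, 9 fell in WT (adjusted p = 7.7e-08) and 9 in KO (adjusted p = 8.0e-08), and 1 more was higher in WT when adjusted over the list alone. The class II transactivator Ciita was at -5.29 ± 0.18 and H2-Eb1 at -4.59 ± 0.12 in WT. Among 19 scavenger, efferocytosis and alternative-activation genes 12 rose and 5 fell in WT (adjusted p = 2.5e-04). Chil3 was at 7.95 ± 0.16 and the efferocytosis receptor Mertk at 2.37 ± 0.053, against its relative Axl at -2.44 ± 0.055. Jaml, a cell adhesion gene, rose from 0.117 ± 0.118 to 91.8 ± 3.27 CPM, the hemoglobin scavenger Hp from 0.192 ± 0.158 to 55.5 ± 3.54 CPM, and Hhipl1 was 1790-fold higher (320 to 70500) in WT. Flt3, a receptor found on dendritic cells and progenitors, was 400-fold higher in WT (137 to 1940) and rose by 8.11 ± 0.33 in KO.

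Growth and biosynthesis genes fell with dexamethasone. All 28 cell cycle genes fell in WT (camera adjusted p = 1.3e-14) and in KO (adjusted p = 4.0e-14), with Top2a at -1.44 ± 0.054 and -1.31 ± 0.053. Of 15 genes of the integrated stress response and serine synthesis, 13 fell in either genotype (adjusted p = 1.9e-05 in WT), such as the folate enzyme Mthfd2 (-1.98 ± 0.083). All 20 cholesterol synthesis genes fell in WT (adjusted p = 2.6e-13), including Fdps (-1.61 ± 0.079), though that list had adjusted p = 0.0520 with an estimated correlation. LXR target genes split into 2 higher and 7 lower in WT (adjusted p = 0.0123), with Apoe at 1.80 ± 0.055 and the cholesterol exporter Abca1 at -1.26 ± 0.051. Chemokines gave 2 higher and 10 lower in WT (adjusted p = 0.0211, and adjusted p = 0.115 with an estimated correlation). The inflammatory list, at trace levels without LPS, was not called in WT (adjusted p = 0.158). Il1b was 29-fold lower in WT (4.77 to 1190) and 8.81-fold lower in KO (2.12 to 78.0), though its KO call was lost without KO control 3 or 4 (-2.51 and -2.69) or KO dexamethasone 2 or 4 (-2.505 and -2.49). Nos2 was at least 6.33-fold lower in WT, from 17 counts to 0. Nos2 in KO differed by -0.81 ± 1.04 (adjusted p = 0.553), and Il6 had 3 counts or fewer in every group without LPS, so no fold is given. Nr3c1 fell by 0.42 ± 0.045 in WT and by 0.41 ± 0.045 in KO. In WT 7132 genes were called (3062 higher and 4070 lower, 1391 by 2-fold or more) and in KO 7004 (3022 higher and 3982 lower). A direct test of the difference between genotypes with edgeR called 0 genes, with 617 at an unadjusted p under 0.05, and DESeq2 also called 0. In that test Acod1 was at -0.06 ± 0.27 and Nr3c1 at 0.01 ± 0.064 (adjusted p = 1 for each). Without library WT control 4 the same test called 3 genes. The interferon-stimulated genes as a group were slightly less lowered in KO (median difference 0.16, no member called over all genes and 6 higher adjusted over the list alone, camera adjusted p = 1.3e-14), and this had adjusted p = 0.121 with an estimated correlation.

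The third comparison asked how dexamethasone changes the LPS response, first in WT. Most inflammatory mediators that LPS had raised were far lower when dexamethasone was present. Il1b fell from 8469 ± 670 to 42.3 ± 5.01 CPM (-7.65 ± 0.076), Nos2 from 3850 ± 328 to 59.96 ± 6.02 CPM (-6.002 ± 0.067) and Il6 from 72.2 ± 6.11 to 6.53 ± 0.825 CPM (-3.47 ± 0.093). Arginase 1, Arg1, from the list with alternative-activation genes, went from 393 ± 106 CPM to 0 counts, at least 10600-fold lower. Of 16 inflammatory cytokines and enzymes, 1 rose and 14 fell (camera adjusted p = 6.1e-06), among them the prostaglandin synthase Ptgs2 (-5.77 ± 0.082). Of 20 chemokines, 3 rose and 17 fell (adjusted p = 6.1e-05), with the monocyte attractants Ccl2 at -7.35 ± 0.14 and Ccl7 at -8.29 ± 0.16 and the neutrophil attractant Cxcl3 at -6.77 ± 0.083. All 31 interferon-stimulated genes fell (adjusted p = 1.4e-15), such as Rsad2 (-3.76 ± 0.072). Of 17 NF-kappaB regulators, 1 rose and 13 fell (adjusted p = 0.0011), with Atf3 at -3.71 ± 0.063 and the deubiquitinase Tnfaip3 higher by 0.62 ± 0.037. Of 11 MHC class II and co-stimulation genes, 1 rose and 9 fell (adjusted p = 6.2e-04). The matrix protease Mmp12 fell from 1698 ± 367 to 2.48 ± 0.321 CPM (-9.41 ± 0.17), the mitochondrial protein gene Mgarp changed by -8.40 ± 0.19 and the activin subunit Inhba by -8.15 ± 0.095. Receptor targets rose, 12 of 18 with 4 lower (adjusted p = 4.8e-04), including Fkbp5 (5.90 ± 0.070), Tns1 (8.09 ± 0.092) and the iron-binding Lcn2 (3.02 ± 0.046). Tmem63c was at least 243-fold higher, Hhipl1 at least 304-fold higher and Dnah12 1490-fold higher (411 to 12300).

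Metabolic genes changed too, glycolysis genes down and TCA cycle genes up. Of 18 glycolysis genes, 1 rose and 16 fell (camera adjusted p = 6.8e-12), with Slc16a3 at -3.24 ± 0.046, Slc2a1 at -3.18 ± 0.050 and lactate dehydrogenase Ldha at -1.93 ± 0.034. All 13 HIF1 targets outside glycolysis fell (adjusted p = 4.9e-12), with the angiogenic factor Vegfa at -5.37 ± 0.073 and Ndrg1 at -5.18 ± 0.073. All 23 genes of the TCA cycle and pyruvate dehydrogenase complex rose (adjusted p = 2.0e-11), led by Idh3a, a subunit of isocitrate dehydrogenase, from 27.7 ± 1.36 to 114 ± 3.14 CPM (2.04 ± 0.052), with Sdha at 1.10 ± 0.031. Of 52 nuclear-encoded oxidative phosphorylation genes, 49 rose and 1 fell (adjusted p = 4.8e-13, and adjusted p = 0.0609 with an estimated correlation), for example Ndufs1 at 1.21 ± 0.043. Mitochondrially encoded mRNAs rose in 10 of 11 cases (adjusted p = 0.0052, and adjusted p = 0.304 with an estimated correlation), beside the higher mitochondrial share of counts given above. NRF2 targets fell in 16 of 19 cases (adjusted p = 5.6e-06, and adjusted p = 0.0527 with an estimated correlation), with Hmox1 at -3.13 ± 0.039. Cholesterol synthesis genes rose in 19 of 20 cases (adjusted p = 5.0e-09, and adjusted p = 0.0895 with an estimated correlation), with Acat2 at 2.11 ± 0.071. Cell cycle genes rose in 27 of 28 cases (adjusted p = 6.8e-12), though Top2a, at 44.5 ± 2.04 CPM, stayed below its control level of 288 ± 12.1 CPM. Scavenger genes split into 10 higher, such as Mertk (4.09 ± 0.074), and 6 lower, such as Cd36 (-3.46 ± 0.079), with a median above 0 and a mean below it (adjusted p = 0.299). Acod1 fell by 1.24 ± 0.041 and Nr3c1 rose by 0.68 ± 0.045. In all 9978 genes were called, 4997 higher and 4981 lower (4966 and 5090 without a filter on low counts, 4844 and 4854 without WT LPS 1, 4870 and 4919 without WT LPS 2), and 3204 by 2-fold or more. The member counts of these lists were identical when adjusted over the list alone. With no normalization the median of all genes shifted by 0.104.

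**Figure D2:**
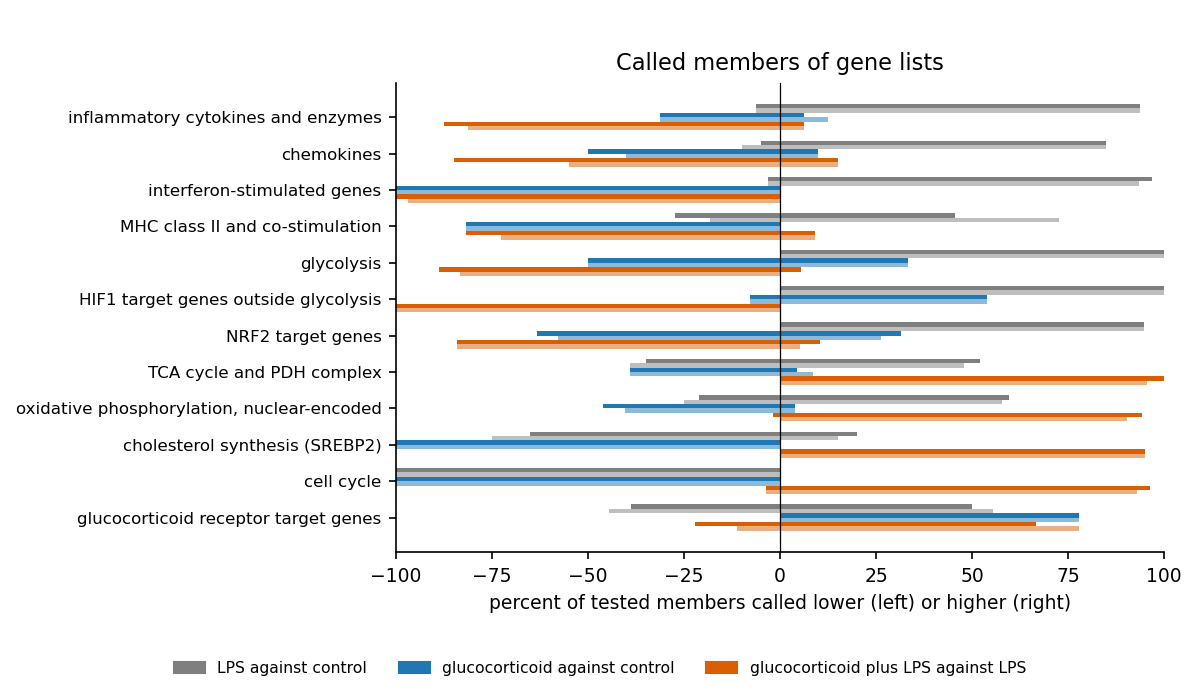
Percent of the tested members of 12 gene lists called lower (left of 0) or higher (right of 0) for LPS against control (grey), dexamethasone against control (blue) and dexamethasone plus LPS against LPS (orange), with dark bars for WT and pale bars for KO. For dexamethasone plus LPS against LPS, glycolysis bars run to the left, with 16 of 18 genes in WT and 15 in KO, and TCA cycle bars to the right, with 23 and 22 of 23.

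In KO the treatment of the same label changed the LPS response far less. Uneven exposure or pooling of these KO samples cannot be told apart from an effect of genotype, as weighed further below. Il1b went from 7072 ± 512 to 4362 ± 439 CPM (-0.70 ± 0.055), Nos2 from 3532 ± 235 to 2228 ± 177 CPM (-0.67 ± 0.052), Il6 from 45.2 ± 4.48 to 29.8 ± 3.21 CPM (-0.60 ± 0.078) and Arg1 from 253 ± 41.2 to 158 ± 16.5 CPM. Inflammatory cytokines and enzymes still fell in 13 of 16 cases (camera adjusted p = 0.0024), but the median log2 fold change was -0.53 against -2.40 in WT. Chemokines fell in 11 of 20 cases and rose in 3 (adjusted p = 0.190), with Ccl3, a macrophage inflammatory protein, higher by 1.04 ± 0.052 and Cxcl3 lower by 0.70 ± 0.058. Of 31 interferon-stimulated genes 30 fell (adjusted p = 4.7e-12), with Rsad2 at -0.60 ± 0.061. Glycolysis genes fell in 15 of 18 cases (adjusted p = 6.9e-14), with Ldha at -0.46 ± 0.033, and all 13 HIF1 targets fell (adjusted p = 1.4e-10), with Vegfa at -0.67 ± 0.053. TCA cycle genes rose in 22 of 23 cases (adjusted p = 1.0e-13), with Idh3a at 1.10 ± 0.054, and oxidative phosphorylation genes in 47 of 52, or 48 adjusted over the list alone (adjusted p = 2.0e-17). Receptor targets rose, 14 of 18 with 2 lower, or 3 lower adjusted over the list alone (adjusted p = 7.3e-11), with Fkbp5 at 4.68 ± 0.071, Tns1 at 6.04 ± 0.087 and Lcn2 at 1.94 ± 0.044. Other large rises were the transcription factor Zbtb16, 313-fold higher (107 to 1520), Dnah12 (8.08 ± 0.28), the sulfotransferase Sult1a1 (7.31 ± 0.18) and the Wnt receptor Fzd4 (6.70 ± 0.27). Among genes that met the naming rule (protein-coding, at least 5 CPM, no overlap between libraries) the steepest falls were shallow, Gstt4 at -0.93 ± 0.20 and Prr15 at -0.86 ± 0.15. The other lists of this paragraph had identical counts when adjusted over the list alone. In all 5499 genes were called, 3000 higher and 2499 lower; of the 565 that passed 2-fold, 511 were higher and 54 lower. With RLE size factors 2664 genes were higher and 3005 lower, and with DESeq2 2697 and 3040, so which direction held more genes depends on the normalization.

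A direct test of the difference in the dexamethasone effect under LPS, KO minus WT, in which each genotype's libraries shared 1 lane, called 6552 genes, 3446 higher and 3106 lower. The larger direction turned with RLE size factors (3137 higher and 3437 lower), with DESeq2 (3148 and 3487) and with no normalization (2901 and 3805). The difference was 6.95 ± 0.090 for Il1b, 5.34 ± 0.081 for Nos2, 2.87 ± 0.12 for Il6, 8.72 ± 0.21 for Mmp12, 7.47 ± 0.12 for Inhba and 7.58 ± 0.20 for Ccl7. By list, the effect was higher in KO, that is less downward or more upward, for 13 of 16 inflammatory genes (camera adjusted p = 2.7e-07), 16 of 20 chemokines with 2 the other way (adjusted p = 1.0e-07), all 31 interferon-stimulated genes (adjusted p = 1.3e-20) and 16 of 18 glycolysis genes (adjusted p = 1.3e-17). The same held for all 13 HIF1 targets (adjusted p = 2.7e-19), with Vegfa at 4.70 ± 0.091. It was lower in KO for 22 of 23 TCA cycle genes (adjusted p = 1.7e-11), with Idh3a at -0.93 ± 0.076 and Sdha at -0.64 ± 0.044. Of 28 cell cycle genes 24 had a lower effect in KO (adjusted p = 3.6e-09), Top2a at -1.46 ± 0.17. For oxidative phosphorylation the effect was lower in 41 of 52, or 44 adjusted over the list alone (adjusted p = 1.5e-09, and adjusted p = 0.134 with an estimated correlation). For cholesterol synthesis it was lower in 19 of 20 (adjusted p = 2.8e-07, and adjusted p = 0.147 with an estimated correlation). Receptor targets gave 5 higher and 9 lower, or 6 and 9 adjusted over the list alone (adjusted p = 0.0129), with Lcn2 at -1.08 ± 0.061 and the glutamine synthetase gene Glul at -0.85 ± 0.053. Acod1 was at 0.90 ± 0.057 and Nr3c1 at -0.33 ± 0.063. With dexamethasone and LPS, Jaml was at 9.27 ± 1.75 CPM in WT and 2.88 ± 0.166 CPM in KO, and Hhipl1 at 12.1 ± 0.812 and 4.11 ± 0.674 CPM.

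**Figure D3:**
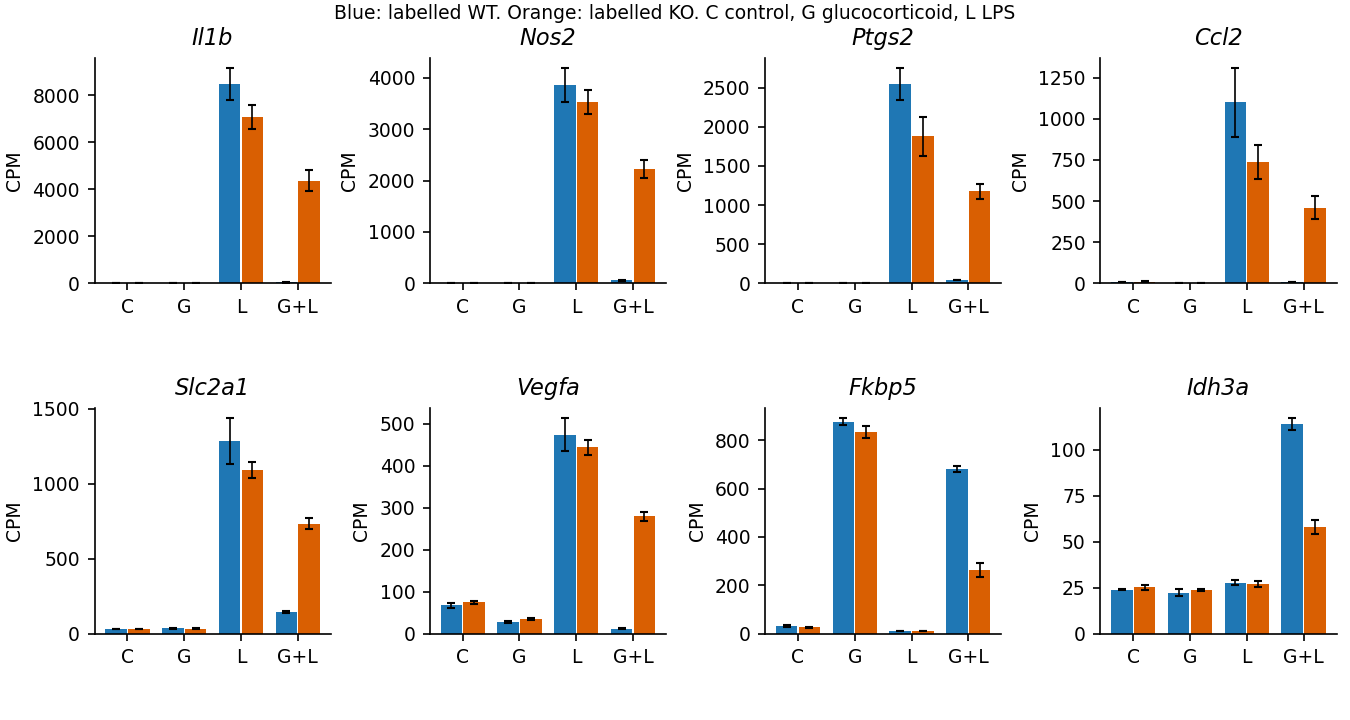
Group means in CPM for Il1b, Nos2, Ptgs2, Ccl2, Slc2a1, Vegfa, Fkbp5 and Idh3a in control (C), dexamethasone (G), LPS (L) and both (G+L), with error bars of 1 SD over 4 libraries, blue for WT and orange for KO. With both treatments Il1b stands at 42.3 CPM in WT and 4362 CPM in KO.

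**Figure D4:**
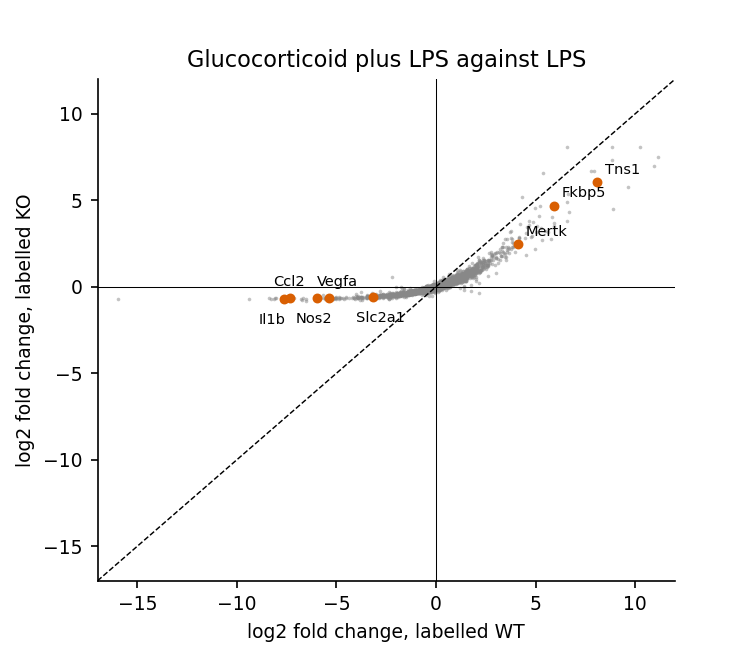
Log2 fold change for dexamethasone plus LPS against LPS in WT (horizontal) and KO (vertical), 1 point per gene that reaches 20 CPM in a group, with equality dashed. Il1b lies at -7.65 in WT and -0.70 in KO and Tns1 at 8.09 and 6.04.

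The fourth comparison set KO against WT within each treatment. Fewer genes differed between the genotypes without LPS than with it. In control, the peptide transporter Slc15a2 was lower in KO (2.59 ± 0.527 against 6.05 ± 0.858 CPM, -1.22 ± 0.16), as were the growth factor Gdf3 (-0.80 ± 0.11), Cnbd2 (-0.43 ± 0.073) and the scavenger receptor Colec12 (-0.43 ± 0.067). Neo1, a netrin receptor family member, was higher (0.82 ± 0.13), as were the stem cell factor receptor Kit (0.60 ± 0.10), Aimp2 (0.55 ± 0.12), Axl (0.50 ± 0.047) and Id3 (0.42 ± 0.10). With dexamethasone, Slc15a2 (-1.24 ± 0.15), Gdf3 (-1.001 ± 0.11) and the metalloprotease Adam19 (-0.73 ± 0.14) were lower, and Axl (0.70 ± 0.058), Fgl2 (0.62 ± 0.098) and Slc5a3 (0.54 ± 0.079) were higher. Interferon-stimulated genes were higher in KO with dexamethasone in 9 of 31 cases, or 15 adjusted over the list alone (camera adjusted p = 5.9e-22, and adjusted p = 0.0566 with an estimated correlation), with Oasl2 at 0.24 ± 0.039. Cell cycle genes were higher in 4 of 28, or 17 adjusted over the list alone (adjusted p = 4.0e-09, and adjusted p = 0.0937 with an estimated correlation). Macrophage identity genes were lower in control in 1 of 14, or 5 adjusted over the list alone (adjusted p = 6.0e-04), the called gene being the lysozyme gene Lyz2 (-0.26 ± 0.042). Il1b differed by -0.67 ± 0.59 in control (adjusted p = 0.83) and Nos2 by -1.26 ± 0.76 (adjusted p = 0.691), and with dexamethasone these genes and Il6 had at most 4 counts over a group. Nr3c1 differed by -0.03 ± 0.046 with dexamethasone (adjusted p = 0.908). In control 78 genes were called (35 higher and 43 lower) and with dexamethasone 130 (78 higher and 52 lower). The counts rose to 121 and 401 with the compared groups fitted alone, to 137 and 201 without a filter on low counts and to 115 and 190 with DESeq2. The larger direction turned in control with no normalization (45 higher and 28 lower), with a lane term (33 and 30), on lane 3 libraries alone (33 and 29) and without WT control 1 or KO control 1, 2 or 4 (25 and 22, 33 and 30, 28 and 27, 25 and 23), and with dexamethasone with the groups fitted alone (198 and 203). With DESeq2 the adjusted p of Id3 was 0.207, and its call was lost without WT control 1, 2 or 3 (0.39, 0.41 and 0.40) or KO control 1, 2, 3 or 4 (0.42, 0.45, 0.38 and 0.43), as was that of Aimp2 without WT control 1 or 3 or KO control 2 (0.51, 0.48 and 0.47). Leaving out 1 library brought the control count down to 47 without WT control 1, 51 without WT control 2 and 48 without KO control 4. The dexamethasone count fell to 80, 84 and 82 without WT replicates 1, 2 and 3 and to 69 and 75 without KO replicates 3 and 4, and to 75 with a term for the sequencing lane.

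With LPS alone, KO had lower inflammatory mediators and chemokines than WT, by less than 2-fold in most cases. Il6 was at 45.2 ± 4.48 CPM against 72.2 ± 6.11 in WT (-0.68 ± 0.074), Il1b at -0.26 ± 0.055 and the granulocyte growth factor Csf3 at -1.23 ± 0.14. Nos2 differed by -0.12 ± 0.052 (adjusted p = 0.134), or by -0.18 without WT LPS 4 (adjusted p = 0.0143) and by -0.125 ± 0.0322 without a filter on low counts (adjusted p = 0.00382), and Il1b had adjusted p = 0.0592 with DESeq2. Inflammatory genes were lower in 8 of 16 cases, or 11 adjusted over the list alone (camera adjusted p = 2.5e-04). Chemokines were lower in 12 of 20, or 14 lower and 1 higher adjusted over the list alone (adjusted p = 1.4e-08), with Ccl9 at -0.71 ± 0.036, Cxcl3 at -0.79 ± 0.057, Cxcl10 at -0.97 ± 0.084 and Ccl7 at -0.94 ± 0.084. Endoplasmic reticulum chaperones were lower in 11 of 15, or 14 adjusted over the list alone (adjusted p = 7.2e-14), with Hspa5, the chaperone BiP, at -0.26 ± 0.027. Genes of the integrated stress response and serine synthesis were lower in 6 of 15, or 9 adjusted over the list alone (adjusted p = 8.1e-06), with asparagine synthetase Asns at -0.44 ± 0.071. Cholesterol synthesis genes were lower in 15 of 20, or 16 adjusted over the list alone (adjusted p = 2.1e-14, and adjusted p = 0.0568 with an estimated correlation), with Sqle at -0.49 ± 0.063. MHC class II genes were higher in 6 of 11 cases and lower in 1 (adjusted p = 0.004, and adjusted p = 0.0659 with an estimated correlation), with H2-Aa at 0.51 ± 0.064. The metallothionein Mt1 was at -1.02 ± 0.049, the collagenase Mmp13 at -1.02 ± 0.071, Arhgap15 at 0.90 ± 0.12, Fgl2 at 0.88 ± 0.098 and Tmem176b at 0.73 ± 0.089. The TCA cycle list was not called (adjusted p = 0.614), and mitochondrially encoded mRNAs were lower in 6 of 11 and higher in 1 (adjusted p = 0.0194, and adjusted p = 0.389 with an estimated correlation). In all 1468 genes were called, 673 higher and 795 lower (721 and 709 with RLE size factors, 799 and 761 with DESeq2, 1016 and 547 with no normalization, 64 and 48 with a lane term). All KO libraries with LPS were sequenced in lane 2 and all WT libraries in lane 3, so these differences come with a difference of lane. A lane term, which rests on 1 library without LPS, left 112 genes and turned Acod1 to 0.19 ± 0.56, Il1b to 2.37 ± 3.26 and Il6 to 1.17 ± 2.18, where that library's group had 2 counts of Il1b and 1 of Il6, and fitting these 2 groups alone gave 667 genes. With the lane term Asns (-0.37, adjusted p = 0.513), Ccl7 (-1.22, adjusted p = 0.833), Csf3 (-1.23, adjusted p = 1), Cxcl10 (-1.34, adjusted p = 0.698) and Cxcl3 (-0.79, adjusted p = 1) were not called, nor were Fgl2 (0.62, adjusted p = 0.0798), H2-Aa (0.56, adjusted p = 0.490) and Mmp13 (-1.02, adjusted p = 0.087).

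The LPS effect itself was tested for a difference, KO minus WT, and 536 genes passed (299 higher and 237 lower). Mt1 rose less in KO (-1.02 ± 0.072), as did Il1rn, the interleukin-1 receptor antagonist (-0.62 ± 0.12), and the uridine phosphorylase Upp1 (-1.69 ± 0.43), and Ccl9 fell more (-0.63 ± 0.050). Chemokines were lower in this difference in 5 of 20 cases, or 7 adjusted over the list alone (camera adjusted p = 7.0e-05), and endoplasmic reticulum chaperones in 9 of 15, or 12 adjusted over the list alone (adjusted p = 2.3e-14), with Hspa5 at -0.30 ± 0.039. Macrophage identity genes were higher in 5 of 14 and lower in 1, or 6 and 1 adjusted over the list alone (adjusted p = 2.0e-05), with Lyz2 at 0.47 ± 0.059 and the lysosomal protease Lgmn at 0.36 ± 0.047. Among the largest rises was Nxpe5 (1.92 ± 0.37), lowered by LPS in either genotype and less so in KO. Acod1 was at 0.40 ± 0.10, Il1b at 0.41 ± 0.59 (adjusted p = 0.83), Nos2 at 1.14 ± 0.76 (adjusted p = 0.535) and Nr3c1 at 0.01 ± 0.064 (adjusted p = 0.966). The Acod1 call was lost without WT control 1 or KO control 3 (0.31 and 0.30) and the Upp1 call without WT control 2 (-1.48). With a lane term 113 genes were called, and with the 4 groups fitted alone 314. The lane term ended the calls of Acod1 (0.998 ± 0.56, adjusted p = 0.614), Il1rn (-0.54 ± 0.37, adjusted p = 0.722), Nxpe5 (1.44 ± 0.43, adjusted p = 0.114) and Upp1 (-1.60 ± 0.76, adjusted p = 0.503).

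With dexamethasone and LPS together, KO and WT differed widely. Il1b was higher in KO by 6.69 ± 0.074, Nos2 by 5.21 ± 0.065, Il6 by 2.19 ± 0.099, the HIF1 target Adm by 6.87 ± 0.22 and Mmp12 by 7.99 ± 0.17, and Arg1 was at least 4210-fold higher. Inflammatory genes were higher in 13 of 16 cases and lower in 2 (camera adjusted p = 2.0e-05), chemokines in 17 and 3 of 20 (adjusted p = 4.3e-05), and all 31 interferon-stimulated genes were higher (adjusted p = 2.9e-19). Glycolysis genes were higher in 16 of 18 (adjusted p = 2.9e-15), with Slc2a1 at 2.37 ± 0.049, and HIF1 targets in all 13 (adjusted p = 1.5e-16). TCA cycle genes were lower in all 23 cases (adjusted p = 6.4e-12), with Idh3a at 58.0 ± 3.66 CPM against 114 ± 3.14 CPM, and cholesterol synthesis genes in all 20 (adjusted p = 2.9e-12). All 15 endoplasmic reticulum chaperones were lower (adjusted p = 2.7e-09), with Herpud1 at -1.21 ± 0.054. Receptor targets were lower in 11 of 18 and higher in 4 (adjusted p = 8.1e-04), with Fkbp5 at -1.38 ± 0.050, and Nr3c1 was at -0.36 ± 0.044. Endothelin 1, Edn1, was at -1.87 ± 0.11 and Tmem63c at -1.84 ± 0.21. In all 8137 genes were called, 4118 higher and 4019 lower (3847 and 4334 with RLE size factors, 3854 and 4336 with DESeq2, 3719 and 4466 with no normalization), and 1590 by 2-fold or more. Here too KO was in lane 2 and WT in lane 3, and with the lane term 4834 genes were called, with Acod1 at 1.09 ± 0.54 (adjusted p = 0.124) and Nos2 at 2.52 ± 2.97 (adjusted p = 0.574). Il6 (4.04 ± 3.43, adjusted p = 0.408), Adm (6.87, adjusted p = 1), Edn1 (-3.10 ± 2.36, adjusted p = 0.347) and Tmem63c (-2.28 ± 2.31, adjusted p = 0.5) were not called with it either. The 27 tested genes within 5 Mb of Acod1 held 0 edgeR calls in control and 0 with dexamethasone (1 and 3 at an unadjusted p under 0.05, and 0 with DESeq2), 6 with LPS (3 higher and 3 lower, 22.2% against 10.2% elsewhere, Fisher's exact p = 0.0503, adjusted p = 0.201) and 12 with both (9 higher and 3 lower, 44.4% against 56.4%, Fisher's exact p = 0.245, adjusted p = 0.490).

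The fifth comparison asked whether LPS changes the response to dexamethasone in WT, as the dexamethasone effect with LPS minus that without. Ddit4, raised 6.64 by dexamethasone alone, was at -0.70 ± 0.082 with LPS, a difference of -7.34 ± 0.14, while Tns1 was raised more (5.79 ± 0.12). All 23 TCA cycle genes (camera adjusted p = 1.2e-11), all 20 cholesterol synthesis genes (adjusted p = 7.7e-14, and adjusted p = 0.0615 with an estimated correlation) and all 28 cell cycle genes (adjusted p = 3.1e-17) responded more upward with LPS than without, for example Fdps (3.41 ± 0.11) and Top2a (5.00 ± 0.11). Glycolysis genes responded more downward in 16 of 18 cases (adjusted p = 2.4e-13), with Slc2a1 at -3.34 ± 0.080, and HIF1 targets in 12 of 13, or 13 adjusted over the list alone (adjusted p = 3.9e-14). Of 16 inflammatory genes, 6 responded more downward and 1 upward (adjusted p = 1.1e-04), with Ptges at -2.04 ± 0.16. Interferon-stimulated genes responded less downward in 20 of 31 cases and more so in 5 (adjusted p = 7.8e-04, and adjusted p = 0.333 with an estimated correlation). Receptor targets gave 6 higher and 11 lower (adjusted p = 0.202). Inhba was at -9.07 ± 0.77 and the receptor gene Tarm1 at -8.14 ± 0.69, while Acod1 was at 2.24 ± 0.16 and Nr3c1 at 1.10 ± 0.064. The differences of Il1b, Il6 and Nos2 had adjusted p of 0.382, 0.598 and 0.644 (0.00766 for Il1b with DESeq2) and rest on at most 1 count over the dexamethasone libraries. In all 8713 genes were called, 4617 higher and 4096 lower.

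The last question was how many LPS-induced genes dexamethasone lowered. In WT, 3266 of the 5393 genes that LPS raised were lowered when dexamethasone was added (60.6%), Il1b, Nos2, Ptgs2 and Slc2a1 among them, where independent calls would give 1862. In KO the number was 1837 of 5310 (34.6%), where independent calls would give 919.8, and 1760 genes were shared by both genotypes. In the other direction, dexamethasone raised 3011 of the 5530 genes that LPS lowered in WT, such as Idh3b and Mertk, and 1921 of 5667 in KO, where independent calls would give 1915 and 1178. The LPS libraries enter both calls, which can create such an overlap on its own, so the overlap of raised genes that dexamethasone lowered was counted again with separate LPS libraries for each call, which left 3027 genes in WT and 1435 in KO; the other direction was not counted again.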

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

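In this part the tests of explanations were chosen only after the results were seen, and so were the counts of other splits for KO against WT in control. In 3 of 82 groups of 4 values 1 library stood far from the other 3, and chance flags about 1 in 20 groups. Acod1 in KO control 3 was at 4.71 CPM, against 6.07 to 6.31 CPM in the other 3 libraries. Saa3 in WT LPS 3 was at 27120 CPM, against 20350 to 21100 CPM. The mitochondrial share of counts in KO LPS 4 was 0.329%, against 0.261% to 0.267%.

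Effects that differed between groups by a direct test were singled out as well. The LPS effect differed between the genotypes in 536 genes (log2 differences, KO minus WT), among them Mt1 (-1.02), Ccl9 (-0.63), Hspa5 (-0.30), Lyz2 (0.47), Lgmn (0.36), Il1rn (-0.62), Nxpe5 (1.92), Acod1 (0.40) and Upp1 (-1.69). The dexamethasone effect under LPS differed in 6552 genes, among them Il1b (6.95), Inhba (7.47), Nos2 (5.34), Vegfa (4.70), Mmp12 (8.72), Ccl7 (7.58), Il6 (2.87), Lcn2 (-1.08), Glul (-0.85), Acod1 (0.90), Sdha (-0.64), Idh3a (-0.93), Top2a (-1.46) and Nr3c1 (-0.33). The dexamethasone effect in WT differed with LPS in 8713 genes (with LPS minus without), among them Ddit4 (-7.34), Tns1 (5.79), Top2a (5.00), Slc2a1 (-3.34), Fdps (3.41), Nr3c1 (1.10), Acod1 (2.24), Ptges (-2.04), Tarm1 (-8.14) and Inhba (-9.07).

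The real counts were set against those of other splits of the compared libraries. For gene counts, 1 of 35 splits, the real one, gave as many genes in each comparison of 2 groups. Every other split mixes the 2 groups, which widens the spread and lowers its count where an effect is large. The labels do not say whether replicates came from separate mice. Chance differences between cell preparations therefore cannot be excluded by these splits. The real count and the highest of the other splits were 10923 and 1830 for LPS in WT, 7132 and 3 for dexamethasone in WT, 9978 and 3332 for dexamethasone under LPS in WT, 10977 and 4, 7004 and 4, and 5499 and 1360 for the same effects in KO. For KO against WT they were 78 and 10 in control, 130 and 1 with dexamethasone, 1468 and 232 with LPS and 8137 and 1 with both. For LPS-induced genes that dexamethasone lowered they were 3266 and 1081 in WT and 1837 and 385 in KO. Among 60 draws, only the real one reached the count for the difference of the LPS effect (536, next 480). The same held for the difference of the dexamethasone effect under LPS (6552, next 6231) and for the difference with against without LPS in WT (8713, next 7388). Some draws came close to these counts. Labels were shuffled within each treatment or LPS state, so a draw can leave the real groups of 1 of them in place. Such a draw keeps part of the real difference. For dexamethasone under LPS the highest draws gave 6231, 6084 and 364, and the rest at most 1. For with against without LPS the highest gave 7388, 7341, 7332 and 4312, and the rest at most 2. The groupings of these draws were not recorded, so 60 draws cannot decide on chance. For the difference of the dexamethasone effect without LPS edgeR and DESeq2 called 0 genes, and 617 had an unadjusted p under 0.05. All 60 draws gave as many, which a real count of 0 fixes in advance, and the highest gave 225.

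For the number of gene lists that camera called, only the real split gave as many for KO against WT with LPS (1 of 35 splits, 16 lists, highest other 12). That too leaves chance differences between cell preparations open. Elsewhere other splits gave as many, which need not mean chance. For the 3 treatment effects and for KO against WT with both, each such split kept 3 of a group's 4 libraries together. These splits hold part of the real difference, so they cannot decide. Splits of 2 and 2 libraries gave at most 4 lists for LPS in WT and 0 for KO against WT with both. For KO against WT in control and with dexamethasone they too gave as many. Random draws can keep part of a grouping too. Chance differences between cell preparations stay open. Of 35 splits, 4 gave as many for LPS in WT (12, highest other 13), 2 for dexamethasone in WT (14 and 14) and 12 for dexamethasone under LPS in WT (15 and 16). For the same effects in KO the number was 11 (11 and 13), 2 (13 and 13) and 10 (13 and 16). For KO against WT the number was 12 in control (4 and 7), 12 with dexamethasone (3 and 5) and 11 with both (15 and 16). Among 60 draws it was 4 for the difference of the LPS effect (11 and 13), 11 for that of the dexamethasone effect without LPS (5 and 8), 9 for that under LPS (15 and 15) and 32 for the difference with against without LPS in WT (12 and 17).

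The smaller effect of dexamethasone under LPS in KO was weighed first, over 315 genes that differ at least 4-fold between KO with LPS and WT with both treatments. Swapped or mislabelled libraries would put single KO libraries at the LPS level or at the WT level with both treatments, but the median weight of the LPS level lay between 0.5862 and 0.6589 in all 4 libraries, so tables argue against this. RNA of WT libraries mixed into the KO ones would raise genes that are low in KO in the other 3 treatments, but 8 of 8 such genes stood under the ratio that a mixture gives (median 0.344 against 0.537), Capn11, named after its values were seen, with 1 count where 27.4 would be present. What stays open is that 1 part of the RNA was at the KO LPS level and the rest at the level of WT with both treatments. The weight was 0.6263 (median, with quartiles 0.6058 and 0.6507), and raised and lowered genes differed by 0.003331. The bootstrap interval, drawn over genes and not libraries, was -0.0118 to 0.0208. A candidate explanation is a like share of cells, cultures or RNA in each KO library that had not met or not answered dexamethasone. These counts do not show whether such a share lies between cells or within every cell. Nor do they separate uneven exposure or pooling of KO samples from an effect of genotype. The design names that effect, which was not tested apart from these.

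The differences between KO and WT with LPS were weighed next. Genotype and lane coincide with LPS, so a lane effect stays open: the lane coefficient, which rests on 1 KO dexamethasone library in lane 2, had a slope of 0.078 on the fold between genotypes, where a lane effect alone would give about 1 and single libraries of the other groups, set against the rest of their group, gave slopes from -0.112 to 0.0858. With a lane term the median absolute log2 fold of the 1468 genes was 0.233 before and 0.231 after, with the median SE going from 0.0534 to 0.104, so calls ended (110 of these genes passed) through the wider error. The folds after the lane term had a slope of 0.922 on those before, 96.73% of the genes kept their sign, and 4 of 14667 genes were called for lane. The slopes, signs and median folds all follow from the same lane coefficient and are not separate evidence. That coefficient comes from 1 library without LPS, so these values cannot decide, and lane and genotype cannot be told apart for these genes. A change around the targeted locus would raise the share of called genes near Acod1; 22.22% of 27 genes were called within 5 Mb against 10.2% elsewhere (Fisher's exact p = 0.0503, adjusted p = 0.201), too few genes to tell, and it would cover only those 27 genes. An effect of the genotype stays open as well.

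The Acod1 reads in KO libraries were weighed last. Single libraries with the wrong genotype label would leave no gene that parts every KO from every WT library, but 18 genes did so in each of the 4 treatments, where chance gives 0.0012 and 100 shuffles of the genotype labels gave at most 0, so tables argue against this. That the KO label was given to mice with an intact Acod1 cannot be told apart from a deletion that leaves a transcript: Acod1 in KO was 58.89% of WT in control and 56.49% with dexamethasone, and 77.05% with LPS and 143.6% with both treatments, where lane and genotype coincide. The control level, called lower in KO (adjusted p = 2.5e-07), goes against Acod1 at the WT level, but a lower level does not show a deletion, and gene-level counts do not show which exons were read.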

How the results depend on the processing

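The lane term and the fits on lane 3 libraries alone were chosen only after the results were seen; the other alternatives were planned, and all could be run. Of 301 alternative counts over 17 results, 274 were within 1.5 times the first count. The exceptions follow, and the cause was not tested unless given. At an adjusted p under 0.01, which is stricter by construction, KO against WT gave 38 genes in control, 62 with dexamethasone and 829 with LPS, and the difference of the LPS effect gave 260. Without a filter on low counts KO against WT gave 137 genes in control and 201 with dexamethasone, and the difference of the dexamethasone effect without LPS gave 6. With the compared groups fitted alone the counts were 121, 401 and 667 genes for KO against WT in control, with dexamethasone and with LPS, 314 for the difference of the LPS effect and 1 for that of the dexamethasone effect without LPS. With the lane term they were 75, 112 and 4834 for KO against WT with dexamethasone, with LPS and with both, and 113 for the difference of the LPS effect; on lane 3 libraries alone KO against WT with dexamethasone gave 72. The lane term takes its information for LPS from 1 library, which widens the errors. With an estimated correlation camera called 89 of 350 list and contrast pairs, in place of 159, and fry called 236.

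Leaving out each library in turn gave 10756 to 10795 genes for LPS in WT, 6670 to 6804 for dexamethasone in WT, 9698 to 9842 for dexamethasone under LPS in WT, 10733 to 10849, 6572 to 6740 and 4862 to 5297 for the same effects in KO. For KO against WT the ranges were 47 to 73 in control, 69 to 119 with dexamethasone, 1152 to 1456 with LPS and 7711 to 7903 with both. The lowest control counts came without WT control 1 (47), WT control 2 (51) and KO control 4 (48), and the lowest dexamethasone counts without WT replicates 1, 2 and 3 (80, 84 and 82) and KO replicates 3 and 4 (69 and 75). For differences of effects the ranges were 427 to 573 for LPS, 0 to 3 for dexamethasone without LPS (3 without WT control 4), 6232 to 6573 for dexamethasone under LPS and 8534 to 8708 for dexamethasone with against without LPS. The overlap ran from 3165 to 3259 in WT and from 1578 to 1826 in KO. Whether replicate numbers mark related libraries was checked by correlating deviations from the group means over 8769 genes. Pairs with the same number had r from -0.113 to 0.145 within a genotype (median 0.0201, 2 of 48 above 0.1). Across genotypes they had r from -0.0981 to 0.227 (median 0.0294, 7 of 64 above 0.1). Pairs with different numbers within a genotype had r from -0.153 to 0.205 (median -0.00825, 4 of 144 above 0.1). Within their genotype 11 of 32 libraries correlated best with their own number. On the second principal component replicates 1 and 3 lay apart from 2 and 4 with LPS in WT (-37.5 and -38.9 against -33.4 and -32.6) and KO (-34.5 and -34.5 against -30.3 and -30.5), so a relation in these groups stays open. With the replicate block dexamethasone under LPS gave 9922 genes in WT and 5455 in KO and their difference 6501, KO against WT gave 92 in control, 168 with dexamethasone and 1545 with LPS, and no named gene changed its call.

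With no normalization, the share of genes called higher moved by more than 10 points for LPS in WT (3863 higher and 7463 lower) and in KO (3864 and 7455), for KO against WT in control (45 and 28) and with LPS (1016 and 547), and for the difference of the LPS effect (371 and 190). The larger direction turned with RLE size factors for LPS in WT (5535 higher and 5409 lower) and KO (5540 and 5414), for dexamethasone under LPS in KO (2664 and 3005), for KO against WT with LPS (721 and 709) and with both (3847 and 4334), and for the difference of the dexamethasone effect under LPS (3137 and 3437). With DESeq2 it turned for the same results, at 5531 and 5415, 5546 and 5422, 2697 and 3040, 799 and 761, 3854 and 4336, and 3148 and 3487. With no normalization it turned for KO against WT in control, with LPS and with both (3719 and 4466) and for the difference of the dexamethasone effect under LPS (2901 and 3805). It also turned with the compared groups fitted alone for LPS in WT (5007 and 4994) and for KO against WT with dexamethasone (198 and 203). Without a filter on low counts and without WT LPS 1 or 2 it turned for dexamethasone under LPS in WT (4966 and 5090, 4844 and 4854, 4870 and 4919). With the lane term it turned for KO against WT in control (33 and 30) and with LPS (64 and 48), and in control also on lane 3 libraries alone (33 and 29) and without WT control 1 or KO control 1, 2 or 4. Over 223 pairs of a named gene and a comparison, 26 changed their call in some setting, and fits on the compared groups alone gave values for 217 pairs, the gene failing their filter in the others. Reversed values came with the lane term in KO against WT with LPS: Acod1 at 0.191, Il1b at 2.371 and Il6 at 1.171, each with an error larger than the value. The lane term ended 22 calls in all, the 3 with reversed values included, leaving out 1 library ended or added calls for 6 pairs, and DESeq2 changed 3. Depth limits the genes at trace level without LPS, such as Il6 with at most 3 counts over 4 libraries.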

Other observations

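The tests in this part of how KO effects scale with WT effects and of genes that separate the genotypes were chosen only after the results were seen. Some gene groups behaved differently from the inflammatory programme. Endoplasmic reticulum chaperones, which fold secreted proteins, were raised by dexamethasone in 12 of 15 cases with 1 lower in WT (camera adjusted p = 7.9e-06, and adjusted p = 0.0778 with an estimated correlation), led by the disulfide isomerase Pdia6 (0.65 ± 0.034). With LPS present 14 of 15 rose (adjusted p = 4.9e-06, and adjusted p = 0.0609 with an estimated correlation). HIF1 targets, which fell with dexamethasone under LPS, rose without LPS in 7 of 13 cases with 1 lower in WT, or 9 and 1 adjusted over the list alone (adjusted p = 0.0211, and adjusted p = 0.312 with an estimated correlation). NRF2 targets split under dexamethasone alone into 6 higher, such as Hmox1 (0.79 ± 0.037), and 12 lower, such as the NADPH-producing enzymes Me1 (-1.47 ± 0.099) and G6pdx (-0.53 ± 0.033), and the list was not called (adjusted p = 0.0837). Of 8 genes of pyruvate entry, 4 rose and 4 fell with dexamethasone under LPS in WT (adjusted p = 0.541), the pyruvate dehydrogenase kinase Pdk1 at -2.01 ± 0.042. These counts were identical adjusted over the list alone except where given.

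Antigen presentation also differed between the genotypes. With dexamethasone and LPS, where genotype and lane coincide, MHC class II and co-stimulation genes were higher in KO in 9 of 11 cases and lower in 1 (camera adjusted p = 2.5e-05), and the counts adjusted over the list alone were identical. Cd74, the invariant chain of class II molecules, fell with dexamethasone alone by 3.67 ± 0.068 in WT and by 3.39 ± 0.065 in KO. Of 3 tested neutrophil markers, 2 rose with dexamethasone in WT (adjusted p = 0.0296, and adjusted p = 0.0575 with an estimated correlation), with the collagenase Mmp8 going from 15.2 ± 2.04 to 95.7 ± 2.49 CPM. Dendritic cell markers gave 1 higher of 4 (adjusted p = 0.492), with a median below 0 and a mean above it, and that gene was Flt3.

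One hypothesis was that every KO cell kept 1 fraction of each log2 effect of dexamethasone under LPS. Raised and lowered genes would then have a like ratio of KO to WT log2 effects. Over 353 genes changed at least 4-fold in WT the median ratio was 0.590 for 116 raised and 0.189 for 237 lowered genes. The difference was 0.4009 (interval 0.375 to 0.422, bootstrap over genes and not libraries), so these values argue against the hypothesis. For 51 genes lowered 16-fold or more in WT, the KO level with both treatments was 0.633 of that with LPS (median; quartiles 0.623 and 0.645). The weight of the LPS level is another measure than this ratio, and only the weight was simulated. Simulated counts gave a weight difference between raised and lowered genes of 8.87e-04 for a mixture and 0.438 for a fraction of each log2 effect. The measured weight difference, over 315 genes, was 0.003331.

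Genes that parted every KO from every WT library in all 4 treatments numbered 18, with 12 lower and 6 higher in KO. Apart from Gdf3, Slc15a2, Colec12 and Neo1 they are named here after their values were seen. Capn11, a calpain gene on chromosome 17, had 68 counts over the WT and 1 over the KO libraries with both treatments. Sdc1 was higher in KO by 0.22, 0.36, 0.26 and 2.17 in control, dexamethasone, LPS and both, and Pltp by 0.07, 0.10, 0.65 and 2.08. Rps4l on chromosome 6 was lower in KO in each treatment (-0.59, -0.96, -0.56 and -0.67).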
